A study of Mus musculus with 8 samples.

How the data were processed

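Messenger RNA of the mouse basal cell carcinoma line ASZ001 was sequenced in 8 libraries, 2 for each of 4 groups. Per the labels' protocols, RNA was extracted with the RNeasy kit and libraries were made from total RNA with the Illumina TruSeq RNA kit, which does not mark strand. Genes that overlap on opposite strands therefore cannot be told apart. Per the series design text, reads were aligned with TopHat and counted with HOMER at the level of transcript isoforms. The submitters' processing notes also list DESeq2 and the genome build mm9, with no versions and no role for DESeq2. The deposited expected counts are not normalized: every value is a multiple of 0.5, and between 47.9% and 49.5% of the values above 0 in a library end in 0.5. The deposited file has 1 entry per gene symbol, 24909 in all, so isoforms were not separated here, and no coordinates are given because the reference at hand is of another build. Of these entries 26 carry symbols that a spreadsheet had turned into dates. They held between 0.218% and 0.246% of the counts of a library and were left out, which left 24883. The ribosomal RNA precursor Rn45s took between 1.62% and 4.08% of a library.

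The deposited counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept where the edgeR function for filtering by expression, with a minimum count of 10 and a minimum total of 15, passed them, which left 12879. Libraries were scaled by the trimmed mean of M-values. The quasi-likelihood test with robust estimation was fitted to all 8 libraries with 1 coefficient per group and 4 residual degrees of freedom, and the common biological coefficient of variation was 0.0596. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called under 0.05. Counts per library size (CPM) use the scaled library sizes, and errors of log2 fold changes were derived from the F statistic.

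Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with a correlation estimated from the data. Of 27 lists, 24 had at least 5 genes tested. Their p-values were adjusted over 96 tests, 24 lists in 4 comparisons, and over a separate 48 tests for the inhibitor groups against the empty vector. A count adjusted over the list alone uses only the members of that list. Marker lists of endothelial cells, leukocytes and melanocytes had too few genes for a list test. The groups, comparisons, tests, gene lists, marker lists and the alternatives below, apart from the omission of Rn45s, were chosen before the data were examined. So was the rule for naming genes. It names Fos, the 8 largest rises and 8 largest falls per comparison (5 and 5 for afatinib against UO126) among called genes with at least 5 CPM in the higher group and no overlap of libraries, without predicted or unnamed transcripts. It also names up to 3 called members per list, or 1 member where none was called, and the inhibitor targets Egfr, Erbb2, Erbb4, Map2k1 and Map2k2. Some genes that the rule names are not reported here.

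Groups of 2 libraries are too small for a count over other splits of the libraries into groups or for a test of outlying libraries. The DMSO libraries were set apart only by using 1 of them in each of 2 comparisons, as values with no test. Between the 2 libraries of a group, the chi-square statistic per degree of freedom was 4.85 for the empty vector, 8.60 with DMSO, 9.17 with afatinib and 25.1 with UO126, so no pair was 1 library deposited under 2 names. The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, a filter of at least 5 CPM in at least 2 libraries, a fit to only the 4 libraries compared and a replicate block. Further alternatives were a fit without robust estimation, adjusted p under 0.01, a 2-fold minimum, fry in place of camera, the estimated correlation and the omission of each library in turn. The omission of Rn45s was chosen after seeing the data. An alternative that would have kept several transcripts per gene was not applicable, since the file has 1 entry per symbol.

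The procedure was tested on simulated counts for the 12879 genes of each comparison. Known changes of 1.5-fold, 2-fold and 4-fold were given to 67, 67 and 66 genes, in 1 draw per comparison. For c-Fos against the empty vector 82.1%, 82.1% and 92.4% of these were recovered, and for afatinib against DMSO 70.1%, 91.0% and 100%. For UO126 against DMSO the shares were 64.2%, 85.1% and 93.9%, and for afatinib against UO126 they were 79.1%, 91.0% and 100%. The share of false calls was 10.5%, 6.45%, 8.47% and 7.69% in the same order, above the nominal 5%. Far more genes were called in the data than were changed in these draws, so the shares need not carry over. In these draws camera called 0, 2, 0 and 1 of 24 lists, adjusted over the 24 lists of each comparison. No list was changed as a whole, but list members could be among the changed genes, so these list calls need not be false. Genes were drawn independently, so the list check does not cover lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.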

Results

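Messenger RNA was profiled in ASZ001, a mouse basal cell carcinoma cell line grown in culture. The cells carried a doxycycline-inducible vector that was either empty or held c-FOS, a subunit of the AP-1 transcription factor. Doxycycline was given for 24 h to every sample. The c-Fos cells then received an inhibitor or its vehicle for 6 h. Afatinib, which blocks the EGFR family of receptor tyrosine kinases, was used at 5 µM. UO126, which blocks the kinases MEK1 and MEK2 below the receptors, was used at 10 µM. The vehicle was DMSO. The 4 groups (empty vector, c-Fos with DMSO, c-Fos with afatinib and c-Fos with UO126) held 2 libraries each, and the label of the empty-vector libraries named doxycycline alone and no vehicle. Total counts per library, to the nearest whole count, lay between 17901974 in c-Fos with DMSO replicate 2 and 23126048 in empty vector replicate 1. No label says whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Levels are given as counts scaled to library size (CPM) as mean ± SD with n = 2, and log2 fold changes are given ± SE.

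Fos itself, the induced gene, was counted in every library. The deposited counts were 937.5 and 1040.5 in the empty-vector libraries. They were 21373 and 19720.5 with DMSO, 22732 and 23573.5 with afatinib and 18209 and 18979 with UO126. Fos stood at 1142 ± 30.2 CPM with DMSO against 45.5 ± 7.0 CPM with the empty vector, a log2 fold change of 4.65 ± 0.096 (edgeR adjusted p = 2.6e-12). Afatinib left a log2 fold change of -0.06 ± 0.080 from DMSO that did not pass the test (adjusted p = 0.57), and with UO126 Fos was lower at -0.44 ± 0.080 (adjusted p = 0.0015). Whether the vector held mouse or human c-FOS is not given in the sources used here, and reads of the vector and of the cells' own gene were not separated. Along the first principal component, which held 51.7% of the variance, the empty-vector libraries lay at -48.4 and -47.5 and all c-Fos libraries between 11.4 and 20.5. The second component, with 26.7%, placed the DMSO libraries at -30.2 and -34.8, the UO126 libraries at 6.30 and 8.14 and the afatinib libraries at 21.1 and 22.2.

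**Figure D1:**
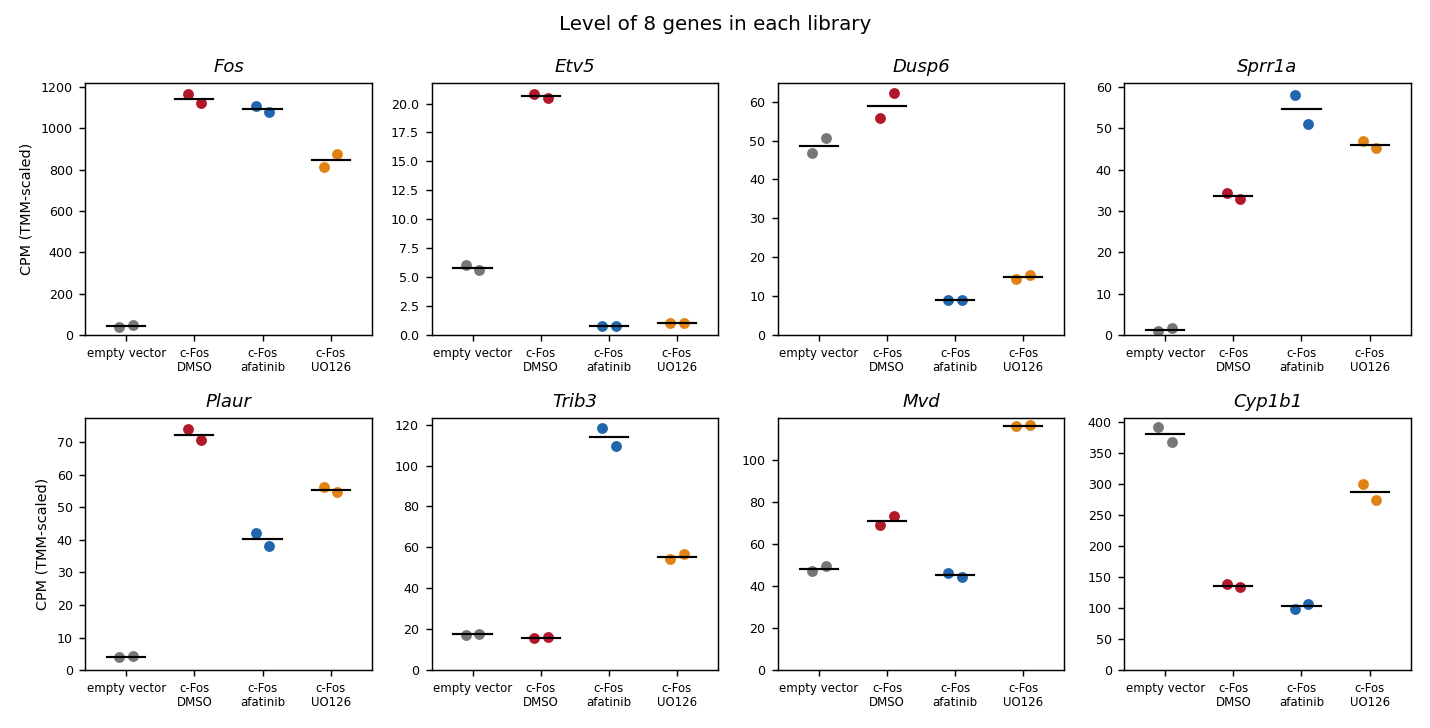
CPM of 8 genes (vertical axes, linear and starting at 0) in each of the 4 groups (horizontal axes). Each point is a library and each bar the mean of 2 libraries. Etv5 lay at 20.6 ± 0.24 CPM with DMSO, at 0.802 ± 0.033 CPM with afatinib and at 1.02 ± 0.0087 CPM with UO126, while Mvd was lower with afatinib and higher with UO126 than with DMSO.

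The comparison of c-Fos with DMSO against the empty vector asks what induction of c-Fos changed in the carcinoma cells, in a study titled around an induced transition from basal to squamous carcinoma. The tested genes of squamous differentiation rose: of 20 tested members of the list, 11 were higher and 0 lower, and 12 were higher when adjusted over the list alone (camera adjusted p = 8.9e-11, and adjusted p = 0.041 with an estimated correlation). Other members had too few counts to be tested, with or without c-Fos. Among them were Krt1, with at most 1 count in any library, and S100a9, with 0 in every library. Sprr1a, which encodes a cornified-envelope precursor, rose from 1.33 ± 0.53 to 33.7 ± 1.1 CPM, a log2 fold change of 4.68 ± 0.16 (adjusted p = 1.5e-10). The desmosomal linker genes Ppl and Evpl rose by 1.62 and 1.39. The Sprr1 genes, Krt6a and Krt6b, and Krt14, Krt16 and Krt17 have close copies that can share reads, so their levels are uncertain. Genes of invasion and matrix remodelling moved in both directions with more rises, 14 higher and 7 lower of 22, or 15 and 7 when adjusted over the list alone (camera adjusted p = 2.4e-15, and adjusted p = 0.071 with an estimated correlation). Among them were Plaur, the urokinase receptor, at 4.13 ± 0.099 and Timp1, an inhibitor of matrix metalloproteinases, at 3.17 ± 0.11.

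Of the AP-1 family other than Fos, Fosl1 rose by 3.97 ± 0.13, while Jun (log2 -0.88) and Atf3 (-0.93) fell, and the list as a whole did not pass the test (2 higher and 2 lower of 8, camera adjusted p = 0.32). The epithelial-mesenchymal transition list was higher, with 6 members higher and 2 lower of 11, or 8 and 2 when adjusted over the list alone (camera adjusted p = 2.9e-04, and adjusted p = 0.12 with an estimated correlation). The members that moved did not all go the way of its name. Vim, an intermediate filament of mesenchymal cells, rose by 4.47 ± 0.093, as did Cldn1, a tight-junction protein of epithelia, by 1.55 ± 0.13, and Cdh2, or N-cadherin, fell by 0.44. Genes downstream of the kinase ERK were higher, 11 up and 3 down of 19 (camera adjusted p = 6.9e-06, and adjusted p = 0.072 with an estimated correlation). Among them were Ccnd1 (1.54 ± 0.063), which encodes cyclin D1, the ETS factor Etv4 (2.40 ± 0.10) and the phosphatase gene Dusp4 (2.88 ± 0.16). In the list of EGFR family receptors and ligands, 8 of 15 were higher and 3 lower, or 8 and 4 when adjusted over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.11 with an estimated correlation). The ligands Tgfa (1.70 ± 0.083) and Hbegf (1.27 ± 0.083) rose, whereas the receptor gene Egfr (-0.95 ± 0.094) and Lrig1 (-1.37 ± 0.077), a negative regulator of the receptors, fell. Of the other inhibitor targets, Erbb2 was at -0.19 ± 0.079 (adjusted p = 0.065) and passed without UO126 replicate 1 (0.014) or 2 (0.029), with no low-count filter (0.028) and with only the compared libraries (0.0097). Map2k1 rose by 0.21 ± 0.072, not called without empty vector replicate 1 (0.097) or 2 (0.093) or DMSO replicate 2 (0.15), with the DESeq2 Wald test (0.062) or with no low-count filter (0.051). Map2k2 rose by 0.23 ± 0.082, not called without empty vector replicate 1 (0.20) or DMSO replicate 1 (0.099) or 2 (0.12), or with a stricter low-count filter (0.053).

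Hedgehog pathway genes, the pathway that drives basal cell carcinoma, were lower with c-Fos, with 1 member higher and 10 lower of 12, or 1 and 11 when adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.28 with an estimated correlation). The co-receptor genes Gas1 (-1.69 ± 0.081), Cdon (-1.06 ± 0.073) and Boc (-0.86 ± 0.11) fell. The list mixes such co-receptors with other pathway genes, and pathway activity was not measured. Type I interferon genes also fell, 0 higher and 12 lower of 14 (camera adjusted p = 5.0e-05, and adjusted p = 0.18 with an estimated correlation). Irf9 was at -1.37 ± 0.14 and Isg15 at -3.00 ± 0.39 from a level of only 3.12 ± 0.91 CPM in the empty vector. FOXO targets were lower, 2 up and 10 down of 15, or 2 and 11 when adjusted over the list alone (camera adjusted p = 2.2e-04, and adjusted p = 0.085 with an estimated correlation). Pik3ip1 was at -1.06 and Sesn3 went from 32.2 ± 5.0 to 16.1 ± 0.61 CPM. YAP/TEAD targets were lower, 4 up and 8 down of 12 (camera adjusted p = 0.011, and adjusted p = 0.48 with an estimated correlation), and Cyr61 fell by 0.98. Sterol synthesis genes were higher, 12 up and 0 down of 18 (camera adjusted p = 0.010, and adjusted p = 0.19 with an estimated correlation). The aryl hydrocarbon receptor targets passed the test narrowly as lower, 2 up and 2 down of 6, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.044, and adjusted p = 0.21 with an estimated correlation). Cyp1b1 and Aldh3a1 both fell by 1.48, and Tiparp rose by 0.64. The list call ended without empty vector replicate 1 (camera adjusted p = 0.058), without DMSO replicate 2 (0.080) or either UO126 replicate (0.054 and 0.053), with no low-count filter (0.27) and with only the 4 compared libraries (0.056).

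Basal and hair follicle keratinocyte markers did not pass the list test (4 higher and 6 lower of 15, camera adjusted p = 0.50), with the integrin gene Itga6 at 1.41 ± 0.067 and the plakin gene Dst at -1.05 ± 0.073. Neither proliferation list passed: 11 of 20 G1/S genes were higher and 3 lower (camera adjusted p = 0.11). Of the G2/M list 2 of 20 were higher and 4 lower, or 1 and 4 when adjusted over the list alone (camera adjusted p = 0.60). Among p53 targets 6 were higher and 1 lower of 12 (camera adjusted p = 0.10), with Cdkn1a, the cell cycle inhibitor p21, at 1.18 ± 0.080. The remaining lists below the test were immediate-early genes (5 up, 3 down of 10, camera adjusted p = 0.29) and cytokines and chemokines (5 up, 3 down of 14, or 6 and 3 over the list alone, camera adjusted p = 0.57). Wnt/beta-catenin targets did not pass either (2 up, 3 down of 6, camera adjusted p = 0.76). Nor did Notch pathway targets (3 up, 1 down of 8, camera adjusted p = 0.53) or lysosome genes (1 up, 7 down of 19, camera adjusted p = 0.23). NRF2 targets were likewise below the test (3 up, 4 down of 11, camera adjusted p = 0.88; median 0.01, mean -0.10, test direction up). In the ATF4 and unfolded protein response list 6 were higher and 5 lower of 20, or 7 and 5 when adjusted over the list alone (camera adjusted p = 0.76), with median 0.03, mean -0.04, test direction down.

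Outside the lists, the largest rises were those of Nlrp2 (log2 6.26 ± 0.22), Siglecg (5.72 ± 0.31), Phex (5.65 ± 0.27), Kcnn4 (5.55 ± 0.16), Inpp4b (5.11 ± 0.25), Nfatc2 (5.10 ± 0.31), Ano1 (5.08 ± 0.16) and Fxyd5 (5.05 ± 0.24). Kcnn4 encodes a calcium-activated potassium channel and stood at 55.9 ± 1.1 CPM with c-Fos. The largest fall was that of Glul, which encodes glutamine synthetase, from 77.2 ± 0.95 CPM in the empty vector, with a log2 fold change of -5.27 ± 0.13 (adjusted p = 4.4e-12). It was followed by Gulp1 (-3.78), Srcin1 (-3.33), Cytip (-3.32), Ptprd (-2.94), Ttc28 (-2.92), Gsta3 (-2.81) and Megf6 (-2.69).

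Markers of other cell types were counted as background. Of 12 fibroblast markers 7 were tested, with 3 higher and 1 lower (camera adjusted p = 0.29): Col1a2 was at 6.41 ± 1.1 CPM with c-Fos against 0.856 ± 0.23 CPM, and Dcn, at 0.717 ± 0.37 against 2.57 ± 0.079 CPM, went the other way. Lum, Thy1 and the leukocyte gene Tyrobp had 0 counts in all 8 libraries. So did Hmgcs1, a sterol synthesis gene missing from the test of its list, so a count of 0 in this file does not show that a transcript was absent. The other markers called were Flt1 (1.53 ± 0.085) and Pecam1 (-0.28 ± 0.068) of 3 endothelial markers tested, Csf1r (3.18 ± 0.49, 1.49 ± 0.66 CPM with c-Fos) of 2 leukocyte markers and Mitf (-0.43 ± 0.14) of 2 melanocyte markers, with 1 higher and 1 lower over the melanocyte list alone. The call of Pecam1 ended without empty vector replicate 1 (adjusted p = 0.072) or DMSO replicate 2 (0.062). That of Mitf ended without empty vector replicate 1 (0.26), DMSO replicate 1 (0.076) or DMSO replicate 2 (0.20).

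In all, 2771 genes were higher and 2662 lower with c-Fos out of 12879 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 494 and 512 of these changed at least 2-fold. The count of lower genes was 1661 without empty vector replicate 1 and 1691 without DMSO replicate 2. Because the empty-vector label names no vehicle, any effect of DMSO is part of this comparison.

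The comparison of afatinib against DMSO asks what blocking the EGFR family for 6 h changed in cells with induced c-Fos. Genes downstream of ERK fell: 15 of 19 were lower and 1 higher, or 16 and 1 when adjusted over the list alone (camera adjusted p = 5.5e-19, and adjusted p = 0.018 with an estimated correlation). The ETS factor Etv5 fell from 20.6 ± 0.24 to 0.802 ± 0.033 CPM, a log2 fold change of -4.67 ± 0.16 (adjusted p = 3.9e-10). Dusp6, the phosphatase that dephosphorylates ERK, changed by -2.73 ± 0.096, and Ccnd1 by -1.60 ± 0.063. G1/S genes fell in 18 of 20 cases with 1 higher, or 19 and 1 when adjusted over the list alone (camera adjusted p = 1.5e-15, and adjusted p = 0.091 with an estimated correlation). The replication licensing genes Cdc6 and Cdt1 were at -1.88 ± 0.094 and -1.42 ± 0.079, and Uhrf1 at -1.14 ± 0.061. The G2/M list did not pass (5 up, 3 down of 20, camera adjusted p = 0.42), and its member Kif11 rose by 0.54.

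In the ATF4 and unfolded protein response list 12 were higher and 5 lower of 20 (camera adjusted p = 4.4e-14, and adjusted p = 0.075 with an estimated correlation). Among the higher members were the pseudokinase gene Trib3, from 15.9 ± 0.40 to 114 ± 6.3 CPM (2.84 ± 0.079), Chac1, a glutathione-degrading enzyme gene, at 2.55 ± 0.074, and Vldlr at 1.66 ± 0.070. FOXO targets rose in 11 of 15 cases with 0 lower, or 12 and 1 when adjusted over the list alone (camera adjusted p = 3.4e-06, and adjusted p = 0.072 with an estimated correlation). Gadd45a was at 1.45 ± 0.084 and Ccng2 at 1.09 ± 0.097. Lysosome genes rose in 13 of 19 cases with 0 lower, or 15 and 0 when adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.091 with an estimated correlation). The autophagy receptor gene Sqstm1 was at 1.12 ± 0.059 and Gpnmb at 1.82 ± 0.17. NRF2 targets rose in 9 of 11 cases with 0 lower (camera adjusted p = 1.6e-06, and adjusted p = 0.091 with an estimated correlation). Hmox1, which encodes a heme oxygenase, was at 1.89 ± 0.11 and Gclc at 0.77 ± 0.065. Sterol synthesis genes fell, 0 up and 8 down of 18 (camera adjusted p = 0.0056, and adjusted p = 0.18 with an estimated correlation). Mvd was at -0.66 ± 0.069 and Cyp51 at -0.61 ± 0.069.

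Immediate-early genes were lower, 1 up and 5 down of 10, or 2 and 6 when adjusted over the list alone (camera adjusted p = 0.0075, and adjusted p = 0.19 with an estimated correlation). Maff was at -2.70 ± 0.12 and Ier3 at -1.02 ± 0.099. That call ended with no low-count filter, at a camera adjusted p of 0.078. In the list of EGFR family receptors and ligands 3 of 15 were higher and 6 lower (camera adjusted p = 0.0093, and adjusted p = 0.14 with an estimated correlation). The ligands Nrg1 (-1.46 ± 0.099) and Hbegf (-0.96 ± 0.081) fell, and the receptor gene Erbb3 rose from 42.8 ± 1.4 to 92.8 ± 1.1 CPM (1.12 ± 0.099). Of the drug's own targets, Egfr rose by 0.44 and Erbb2 by 0.27, the latter without a call when DMSO replicate 2 was left out (adjusted p = 0.11), and Erbb4 held at most 1 count in any library.

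The squamous list, raised by c-Fos, moved in both directions with afatinib, 6 up and 4 down of 20 (camera adjusted p = 0.76). Sprr1a rose further by 0.69 ± 0.10 and Krt16, a keratin of activated keratinocytes, by 0.61 ± 0.081, while Evpl fell by 0.60. Invasion genes likewise split into 9 higher and 8 lower of 22 (camera adjusted p = 0.88). Hmga2 changed by -3.22 ± 0.19, whereas the matrix metalloproteinase gene Mmp10 rose by 1.28 ± 0.095. In the AP-1 family 3 of 8 were higher and 3 lower (camera adjusted p = 0.61), with Fosl1 at -2.01 ± 0.10, Fosl2 at 0.95 ± 0.066 and Atf3 at 1.33 ± 0.095. Vim, in an epithelial-mesenchymal transition list below the test (0 up, 4 down of 11, camera adjusted p = 0.14), fell by 1.08. Of the Hedgehog genes, 7 were higher and 2 lower of 12 (camera adjusted p = 0.61), with Cdon at 1.07 ± 0.073 and Ccnd2 at -1.01 ± 0.060.

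The other lists did not pass. Among them were basal and hair follicle markers (3 up, 7 down of 15, or 4 and 7 over the list alone, camera adjusted p = 0.43) and cytokines and chemokines (2 up, 4 down of 14, or 2 and 5 over the list alone, camera adjusted p = 0.37). YAP/TEAD targets did not pass (3 up, 6 down of 12, camera adjusted p = 0.10), and passed as lower without DMSO replicate 2 (0.031). The same held for Wnt/beta-catenin targets (1 up, 1 down of 6, camera adjusted p = 0.39; median 0.20, mean -0.12, test direction down) and Notch targets (1 up, 3 down of 8, camera adjusted p = 0.33). The test was also not passed by aryl hydrocarbon receptor targets (3 up, 1 down of 6, camera adjusted p = 0.90). Nor was it by p53 targets (5 up, 1 down of 12, camera adjusted p = 0.10) or interferon genes (5 up, 0 down of 14, camera adjusted p = 0.13). Fibroblast markers did not pass (1 up, 1 down of 7, or 0 and 1 over the list alone, camera adjusted p = 0.76). Pdgfra was the higher and Col1a2 the lower, and neither was called with the DESeq2 Wald test (adjusted p = 0.20 and 0.11). Among members of these lists, Vegfa rose by 1.28 ± 0.084, Ctgf changed by -1.87 ± 0.087, Cdkn1a rose by 1.33 ± 0.071 and the leukocyte marker Csf1r rose by 1.30 ± 0.27 to 3.71 ± 0.26 CPM. Of the 3 endothelial markers tested, Tek was higher (1.35 ± 0.41) and Flt1 lower (-0.23 ± 0.080), and the call of Tek ended without DMSO replicate 2 (adjusted p = 0.16) or afatinib replicate 1 (0.18). That of Flt1 ended without DMSO replicate 1 (0.29) or 2 (0.055) or afatinib replicate 1 (0.16) or 2 (0.18). With the DESeq2 Wald test neither was called (0.061 and 0.070). Of the melanocyte markers 0 of 2 were called.

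Among single genes, Fgf21, a hormone of the fasting response, rose from 0.331 ± 0.15 to 9.57 ± 1.3 CPM, a log2 fold change of 4.82 ± 0.27 (adjusted p = 2.1e-08). Fut1 (3.69), Fam180a (2.47), Il17rb (2.47), the alanine aminotransferase gene Gpt2 (2.44) and the glycine transporter gene Slc6a9 (2.38) followed. Besides Etv5 and Dusp6, the largest falls were those of Rgs16 (-4.57), Hmga2, Serpinb10 (-3.07), Tcf7 (-3.07), Maff and Htr5b (-2.59). In all, 2725 genes were higher and 2772 lower with afatinib, 346 and 279 of them at least 2-fold. The count of lower genes was 1692 without DMSO replicate 2 and 1749 without afatinib replicate 2.

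The comparison of UO126 against DMSO asks the same of MEK inhibition. Genes downstream of ERK fell again, 15 lower and 2 higher of 19, or 16 and 2 when adjusted over the list alone (camera adjusted p = 4.3e-24, and adjusted p = 0.017 with an estimated correlation). Etv5 was at -4.33 ± 0.15, Dusp6 at -1.98 ± 0.089 and Ccnd1 at -1.30 ± 0.063. G1/S genes fell in 17 of 20 cases with 0 higher, or 19 and 0 when adjusted over the list alone (camera adjusted p = 4.1e-15, and adjusted p = 0.091 with an estimated correlation). Cdc6 was at -1.12 ± 0.088 and Uhrf1 at -0.85 ± 0.061. The list of EGFR family receptors and ligands was lower, 1 up and 6 down of 15, or 2 and 6 when adjusted over the list alone (camera adjusted p = 7.0e-04, and adjusted p = 0.091 with an estimated correlation). The ligand genes Nrg1 (-1.17 ± 0.096), Tgfa (-0.90 ± 0.079) and Hbegf (-0.71 ± 0.080) were among the lower members. The transcripts of the drug's targets did not pass the test, with Map2k1 at -0.09 ± 0.072 (adjusted p = 0.40) and Map2k2 at -0.12 ± 0.082 (adjusted p = 0.32). Map2k2 passed as lower without UO126 replicate 2, at an adjusted p of 0.034. Egfr, at 0.23 ± 0.095 (adjusted p = 0.092), passed as higher without DMSO replicate 1 (0.030) and with no low-count filter (0.018).

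Sterol synthesis genes rose, 12 up and 0 down of 18 (camera adjusted p = 7.1e-08, and adjusted p = 0.075 with an estimated correlation). Lss, which makes lanosterol, went from 132 ± 0.97 to 221 ± 0.020 CPM (0.74 ± 0.059), and the mevalonate pathway gene Mvd rose by 0.71 ± 0.066. The ATF4 and unfolded protein response list rose in 14 of 20 cases with 0 lower (camera adjusted p = 5.0e-19, and adjusted p = 0.072 with an estimated correlation). Trib3 was at 1.80 ± 0.080, Chac1 at 1.67 ± 0.074 and Vldlr at 1.13 ± 0.070. NRF2 targets rose, 6 up and 0 down of 11 (camera adjusted p = 4.0e-04, and adjusted p = 0.14 with an estimated correlation), with Srxn1 at 0.62 ± 0.069. FOXO targets were higher, 8 up and 1 down of 15, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.093 with an estimated correlation), with Gadd45a at 0.94 ± 0.085. Aryl hydrocarbon receptor targets rose, 4 up and 0 down of 6 (camera adjusted p = 6.6e-04, and adjusted p = 0.091 with an estimated correlation). The cytochrome P450 gene Cyp1b1 was at 1.08 ± 0.070. Lysosome genes were higher, 5 up and 0 down of 19, or 4 and 0 when adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.23 with an estimated correlation), with Sqstm1 at 0.67 ± 0.059. Interferon genes were higher, 3 up and 0 down of 14, or 7 and 0 when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.34 with an estimated correlation). Stat2 was at 0.81 ± 0.085, and the list lost its call without UO126 replicate 1, at a camera adjusted p of 0.056.

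The squamous list passed narrowly as higher, 7 up and 1 down of 20 (camera adjusted p = 0.048, and adjusted p = 0.19 with an estimated correlation). Krt16 was at 1.12 ± 0.081, Ppl at 0.43 ± 0.056 and Evpl at -0.69 ± 0.058. Its call ended without empty vector replicate 1 (camera adjusted p = 0.058), empty vector replicate 2 (0.058) or DMSO replicate 1 (0.099). It also ended with a stricter (0.13) or no (0.098) low-count filter, without robust estimation (0.058) and without Rn45s (0.0504). Wnt/beta-catenin targets were lower by the test, 1 up and 2 down of 6 (camera adjusted p = 0.041, and adjusted p = 0.41 with an estimated correlation). Tcf7 was at -3.49 ± 0.20 and Axin2, a feedback gene of the pathway, at 0.57 ± 0.20 in the other direction. That list's call ended without DMSO replicate 1 (camera adjusted p = 0.18) or UO126 replicate 1 (0.18), with DESeq2 (0.12) and with no low-count filter (0.52). The call of Axin2 ended with any 1 of the empty-vector or afatinib libraries left out, without DMSO replicate 2 (adjusted p = 0.37) and without UO126 replicate 2 (0.19). It also ended with DESeq2 (0.11), with only the compared libraries (0.083) and without robust estimation (0.054). Neither invasion genes (6 up, 7 down of 22, or 8 and 7 over the list alone, camera adjusted p = 0.76; median 0.06, mean -0.06, test direction down) nor Hedgehog genes (4 up, 3 down of 12, or 5 and 3 over the list alone, camera adjusted p = 0.71; median 0.19, mean 0.06, test direction down) passed. Hmga2 changed by -2.71 ± 0.18, Itga3 by -0.66 ± 0.066, Ccnd2 by -1.12 ± 0.060 and Cdon by 0.65 ± 0.074.

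The other lists below the test were the AP-1 family (3 up, 3 down of 8, camera adjusted p = 0.66; median 0.02, mean -0.02, test direction up) and immediate-early genes (4 up, 3 down of 10, or 4 and 4 over the list alone, camera adjusted p = 0.61; median 0.08, mean -0.06, test direction down). Basal markers did not pass (3 up, 4 down of 15, or 4 and 5 over the list alone, camera adjusted p = 0.66; median -0.12, mean 0.0029, test direction down). The same held for epithelial-mesenchymal transition genes (0 up, 3 down of 11, camera adjusted p = 0.061, but 0.029 without DMSO replicate 2 and 0.032 without UO126 replicate 1) and cytokines (3 up, 3 down of 14, or 3 and 4 over the list alone, camera adjusted p = 0.93; median -0.16, mean -0.08, test direction up). It held for G2/M genes (3 up, 0 down of 20, camera adjusted p = 0.40) and YAP/TEAD targets (2 up, 5 down of 12, camera adjusted p = 0.20, but 0.0499 without DMSO replicate 2; median 0.02, mean -0.12, test direction down). Notch targets (2 up, 0 down of 8, or 3 and 1 over the list alone, camera adjusted p = 0.53) and p53 targets (4 up, 1 down of 12, camera adjusted p = 0.12, but 0.040 without UO126 replicate 2) did not pass. Neither did fibroblast markers (1 up, 0 down of 7, or 0 and 0 over the list alone, camera adjusted p = 0.60). The marker called was Pdgfra, a call that ended with the DESeq2 Wald test (adjusted p = 0.24) and with only the compared libraries (0.082). Fosl1 changed by -1.17 ± 0.094, Fosl2 by 0.78 ± 0.066, Egr1 by 1.07 ± 0.14, Vim by -0.89 ± 0.069, Ptgs2 by 1.35 ± 0.16 and Cdkn1a by 1.13 ± 0.071. The leukocyte marker Csf1r rose from 1.49 ± 0.66 to 3.46 ± 0.59 CPM, a call that ended without DMSO replicate 2 (adjusted p = 0.066). Of 3 endothelial markers Flt1 was lower (-0.38 ± 0.081), and 0 of 2 melanocyte markers were called, or 1 when adjusted over the list alone. That was Mitf, at 0.41 ± 0.14 (adjusted p = 0.062), which passed over all genes without empty vector replicate 1 (0.033) or 2 (0.026) or UO126 replicate 2 (0.0035). It also passed with DESeq2 (0.021), with no low-count filter (5.6e-05), with only the compared libraries (0.034) and without robust estimation (0.039).

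Among single genes the largest rises were those of Fut1 (2.70 ± 0.16), Glul (1.94 ± 0.17), Il17rb (1.84 ± 0.19), Trib3, Nrep (1.75 ± 0.11), Gfra2 (1.68 ± 0.16), Chac1 and Ppargc1a (1.67 ± 0.12). Glul, the gene with the largest fall under c-Fos, came to 7.72 ± 0.82 CPM with UO126, against 77.2 ± 0.95 CPM in the empty vector. Etv5, Tcf7, Htr5b (-3.08), Hmga2, Serpinb10 (-2.32), Rgs16 (-2.13), Lgr6 (from 5.29 ± 0.71 to 1.32 ± 0.48 CPM) and Dusp6 had the largest falls. UO126 raised 1788 genes and lowered 1893, 202 and 146 of them at least 2-fold. Without DMSO replicate 2 the counts were 913 and 968.

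**Figure D2:**
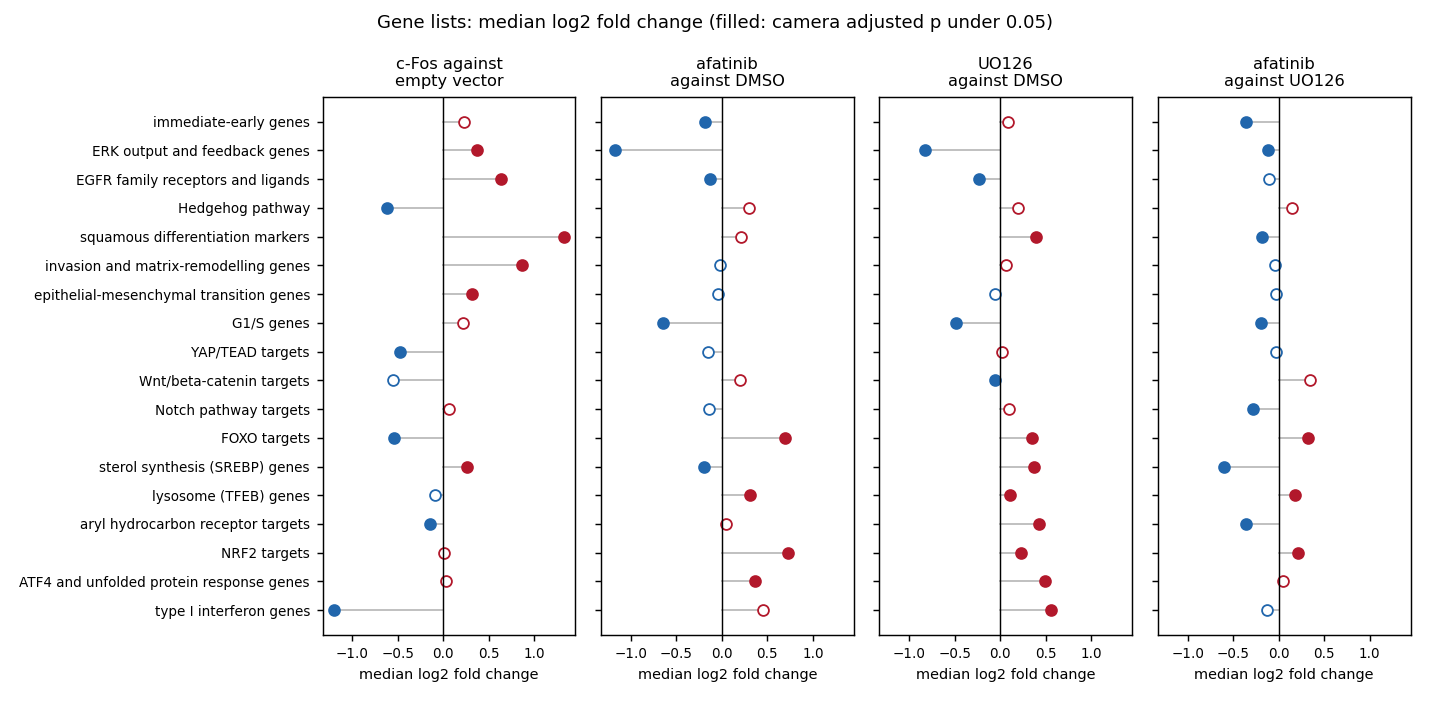
Median log2 fold change (horizontal axes) of the 18 gene lists that passed the list test in at least 1 of the 4 comparisons (vertical axis). Points are filled where the camera adjusted p was under 0.05. Sterol synthesis genes had a median of -0.20 with afatinib and 0.37 with UO126, while the ERK list had medians of -1.17 and -0.83.

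The direct comparison of afatinib against UO126, at 5 and 10 µM for 6 h each, tests where the 2 inhibitors differed. The drugs act at different levels of the pathway and were given at different concentrations. Sterol synthesis genes were lower with afatinib, 0 higher and 15 lower of 18, or 0 and 17 when adjusted over the list alone (camera adjusted p = 1.3e-39, and adjusted p = 0.017 with an estimated correlation). Mvd stood at 45.1 ± 1.5 CPM with afatinib and 116 ± 0.32 CPM with UO126 (-1.36 ± 0.067, adjusted p = 1.3e-07), and Lss (-1.04 ± 0.060) and Fdft1 (-0.91 ± 0.064) went the same way. Aryl hydrocarbon receptor targets were lower with afatinib, 1 up and 3 down of 6, or 1 and 4 when adjusted over the list alone (camera adjusted p = 9.5e-06, and adjusted p = 0.075 with an estimated correlation). Cyp1b1 was at -1.48 ± 0.070 and Tiparp at -0.72 ± 0.10. Immediate-early genes were lower with afatinib, 1 up and 7 down of 10, or 1 and 8 when adjusted over the list alone (camera adjusted p = 1.4e-05, and adjusted p = 0.091 with an estimated correlation). Ier3 was at -1.09 ± 0.097 and Maff at -1.05 ± 0.14.

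The ERK list (0 up, 5 down of 19, or 1 and 6 over the list alone, camera adjusted p = 0.020, and adjusted p = 0.15 with an estimated correlation) and the G1/S list (1 up, 8 down of 20, or 1 and 11 over the list alone, camera adjusted p = 2.3e-04, and adjusted p = 0.32 with an estimated correlation) were further down with afatinib. Dusp6 differed by -0.75 ± 0.10 and Cdc6 by -0.76 ± 0.098, and Ccnd1 by -0.30 ± 0.062, a call that ended without afatinib replicate 2 (adjusted p = 0.076). The ERK list lost its call without UO126 replicate 1 (camera adjusted p = 0.053). Notch targets (0 up, 4 down of 8, camera adjusted p = 0.0019, and adjusted p = 0.12 with an estimated correlation) and squamous markers (0 up, 5 down of 20, camera adjusted p = 0.040, and adjusted p = 0.18 with an estimated correlation) were also lower. The Notch ligand gene Jag1 was at -0.72 ± 0.074, Krt6a at -0.73 ± 0.067 and Krt16 at -0.51 ± 0.080. The squamous call ended without afatinib replicate 1 (0.062), without UO126 replicate 2 (0.057) and with no low-count filter (0.13). Higher with afatinib were lysosome genes (5 up, 0 down of 19, or 8 and 0 over the list alone, camera adjusted p = 6.0e-06, and adjusted p = 0.085 with an estimated correlation) and FOXO targets (6 up, 0 down of 15, or 7 and 0 over the list alone, camera adjusted p = 2.6e-05, and adjusted p = 0.075 with an estimated correlation). NRF2 targets were higher as well (6 up, 0 down of 11, or 7 and 0 over the list alone, camera adjusted p = 8.3e-05, and adjusted p = 0.12 with an estimated correlation). Examples were Gpnmb, 2.29-fold higher, Gadd45a at a log2 difference of 0.51 ± 0.077 and Hmox1 at 0.99 ± 0.098.

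No other list passed. Members of the ATF4 and unfolded protein response list went both ways, 8 up and 6 down of 20, or 9 and 8 over the list alone (camera adjusted p = 0.096), and passed as higher without afatinib replicate 2 (0.0037). The remaining results were AP-1 family (2 up, 2 down of 8, or 3 and 2 over the list alone, camera adjusted p = 0.76) and EGFR family receptors and ligands (2 up, 0 down of 15, or 2 and 4 over the list alone, camera adjusted p = 0.79). They included Hedgehog genes (4 up, 0 down of 12, or 5 and 1 over the list alone, camera adjusted p = 0.096, but 0.041 without afatinib replicate 1 and 0.028 without UO126 replicate 2) and basal markers (2 up, 5 down of 15, camera adjusted p = 0.42). For invasion genes the counts were 6 up and 4 down of 22, or 6 and 5 over the list alone (camera adjusted p = 0.83; median -0.04, mean 0.04, test direction up). Epithelial-mesenchymal transition genes had 0 higher and 0 lower of 11 (camera adjusted p = 0.87). Cytokines (1 up, 4 down of 14, or 1 and 5 over the list alone, camera adjusted p = 0.056, but 0.022 without afatinib replicate 2 and 5.8e-05 without UO126 replicate 2) and G2/M genes (1 up, 0 down of 20, camera adjusted p = 0.76; median -0.02, mean 0.01, test direction up) did not pass. YAP/TEAD targets (3 up, 4 down of 12, camera adjusted p = 0.26) and Wnt/beta-catenin targets (0 and 0 of 6, camera adjusted p = 0.29) were below the test. So were p53 targets (0 up, 2 down of 12, or 4 and 2 over the list alone, camera adjusted p = 0.43) and interferon genes (1 up, 0 down of 14, camera adjusted p = 0.61). Fibroblast markers did not differ by the list test (0 up, 1 down of 7, or 0 and 2 over the list alone, camera adjusted p = 0.14), and 0 of the 3 endothelial, 2 leukocyte and 2 melanocyte markers were called. Over the melanocyte list alone, both were lower.

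Single genes with the largest differences were Acot2 (1.33 ± 0.14), the cholesterol exporter gene Abca1 (1.32 ± 0.16), Klf2 (1.21 ± 0.16), Gpnmb and Mmp13 (1.13 ± 0.12) on the higher side with afatinib. On the lower side they were Cyp1b1, Mslnl (-1.44 ± 0.17), Rhov (-1.39 ± 0.17), Thbs1 (-1.39 ± 0.072) and Mvd. Fos was higher with afatinib by 0.37 ± 0.080 (adjusted p = 0.0084), a call that ended without afatinib replicate 1 (0.064). Erbb2 was higher by 0.27 ± 0.078 (adjusted p = 0.034), not called without empty vector replicate 1 (0.055), afatinib replicate 1 (0.14) or 2 (0.13) or UO126 replicate 1 (0.13), or with only the compared libraries (0.094). In all, 919 genes were higher and 920 lower with afatinib than with UO126, 26 and 50 of them at least 2-fold. These counts were 432 and 403 without afatinib replicate 1, 391 and 307 without afatinib replicate 2, and 481 and 505 when only the 4 libraries of the 2 groups were fitted.

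The last comparison asks how far the inhibitors moved the genes that c-Fos had changed. Of the 2771 genes that were higher with c-Fos, 1324 (47.8%) were lower with afatinib and 354 were raised further, and 1049 (37.9%) were lower with UO126 and 263 raised further. Of the 2662 genes that were lower with c-Fos, 1192 (44.8%) were higher with afatinib and 183 lower still, and 850 (31.9%) were higher with UO126 and 134 lower still. Without DMSO replicate 2 the counts that changed direction were 695 and 652 for afatinib and 493 and 366 for UO126. Without empty vector replicate 1 the c-Fos-lowered genes that rose were 770 and 566. Ccnd1 came to 219.8 ± 4.0 CPM with afatinib and 270.3 ± 14 CPM with UO126, against 665 ± 31 with DMSO and 228 ± 3.6 in the empty vector. Etv5, at 5.82 ± 0.34 CPM in the empty vector, fell below that level with both drugs. Fos RNA itself was called lower with UO126 than with DMSO, but not with afatinib, as given above.

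Of the list calls in the 4 comparisons above, 4 held with an estimated correlation. They were squamous genes with c-Fos, ERK genes with each inhibitor and sterol genes between the inhibitors.

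Of all 2771 genes raised by c-Fos, 1401 (50.6%) were still higher than the empty vector with afatinib and 1498 (54.1%) with UO126, against 85.4% and 85.2% in simulations with the c-Fos effect and no inhibitor effect. Their median log2 difference from it was 0.42 with DMSO, 0.24 with afatinib and 0.27 with UO126, where the simulations gave 0.44 for afatinib and 0.43 for UO126. Of the 2662 lowered genes, 1333 (50.1%) and 1512 (56.8%) were still lower, against 84.3% and 84.7% in the simulations. Their medians were -0.50 with DMSO, -0.28 with afatinib and -0.33 with UO126, where the simulations gave -0.50 for both inhibitors. Among the 494 genes that c-Fos raised at least 2-fold, the median log2 difference from the empty vector was 1.65 with DMSO, 1.53 with afatinib and 1.55 with UO126, and 402 (81.4%) and 423 (85.6%) of them were still higher than in the empty vector. The simulations with no inhibitor effect gave 1.59 for both inhibitors and 94.2% for both. Among the 512 genes lowered at least 2-fold, the medians were -1.43 with DMSO and -0.97 with either inhibitor, and 359 (70.1%) and 379 (74.0%) were still lower. The simulations gave -1.39 and 91.5% for afatinib and -1.38 and 91.6% for UO126. These genes were selected on the DMSO libraries, which raises the size of the DMSO medians by chance. The squamous list remained higher than in the empty vector, with 11 members higher and 0 lower of 20 with afatinib (camera adjusted p = 2.0e-10, and adjusted p = 0.045 with an estimated correlation). With UO126 they were 13 and 0, or 14 and 0 over the list alone (camera adjusted p = 6.6e-16, and adjusted p = 0.035 with an estimated correlation). Invasion genes were also higher than in the empty vector under both drugs, 14 up and 5 down of 22 with afatinib, or 14 and 6 over the list alone (camera adjusted p = 3.1e-13, and adjusted p = 0.046 with an estimated correlation). The invasion counts with UO126 were 15 up and 6 down (camera adjusted p = 4.7e-15, and adjusted p = 0.046 with an estimated correlation). Hedgehog genes were lower than in the empty vector, 1 up and 6 down of 12 with afatinib (camera adjusted p = 6.8e-04, and adjusted p = 0.32 with an estimated correlation). With UO126 the Hedgehog list had 1 up and 8 down, or 1 and 9 over the list alone (camera adjusted p = 1.6e-06, and adjusted p = 0.26 with an estimated correlation). Interferon genes were lower under both, 1 up and 9 down of 14 in each, or 1 and 10 over the list alone with UO126 (with afatinib camera adjusted p = 0.017, and adjusted p = 0.29 with an estimated correlation, and with UO126 camera adjusted p = 0.017, and adjusted p = 0.30 with an estimated correlation). The ERK list was below the empty vector, 4 up and 10 down of 19 with afatinib, or 4 and 11 over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.11 with an estimated correlation). With UO126 its counts were 6 up and 8 down, or 6 and 9 over the list alone (camera adjusted p = 0.027, and adjusted p = 0.22 with an estimated correlation). Sterol synthesis genes were above the empty vector with UO126, 16 up and 0 down of 18 (camera adjusted p = 1.3e-11, and adjusted p = 0.046 with an estimated correlation), while with afatinib 3 were up and 3 down (camera adjusted p = 0.96; median -0.02, mean -0.01, test direction up).

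Both inhibitors left G1/S genes below the empty vector, 0 up and 15 down of 20 with afatinib, or 0 and 16 over the list alone (camera adjusted p = 3.4e-07, and adjusted p = 0.26 with an estimated correlation). With UO126 the counts of G1/S genes were 0 and 15 (camera adjusted p = 3.7e-04, and adjusted p = 0.29 with an estimated correlation). ATF4 and unfolded protein response genes were higher, 13 up and 3 down of 20 with afatinib, or 14 and 3 over the list alone (camera adjusted p = 7.0e-10, and adjusted p = 0.11 with an estimated correlation). With UO126 they were 14 and 1, or 14 and 2 over the list alone (camera adjusted p = 2.7e-09, and adjusted p = 0.11 with an estimated correlation). NRF2 targets were higher, 8 up and 1 down of 11 with afatinib (camera adjusted p = 1.6e-05, and adjusted p = 0.11 with an estimated correlation) and 5 and 1 with UO126, or 7 and 1 over the list alone (camera adjusted p = 0.0089, and adjusted p = 0.26 with an estimated correlation). The p53 targets were higher, 6 up and 1 down of 12 with afatinib, or 7 and 1 over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.11 with an estimated correlation). With UO126 the p53 counts were 6 and 1, or 7 and 3 over the list alone (camera adjusted p = 0.0026, and adjusted p = 0.11 with an estimated correlation). The epithelial-mesenchymal transition list was higher, 6 up and 2 down of 11 with afatinib (camera adjusted p = 0.031, and adjusted p = 0.27 with an estimated correlation) and 5 and 3 with UO126 (camera adjusted p = 0.016, and adjusted p = 0.26 with an estimated correlation). YAP/TEAD targets were lower, 1 up and 5 down of 12 with afatinib (camera adjusted p = 8.0e-05, and adjusted p = 0.27 with an estimated correlation). With UO126 they were 2 and 7, or 2 and 8 over the list alone (camera adjusted p = 1.8e-04, and adjusted p = 0.28 with an estimated correlation). Lysosome genes passed as higher with afatinib, 10 up and 2 down of 19 (camera adjusted p = 0.020, and adjusted p = 0.26 with an estimated correlation), and Wnt/beta-catenin targets as lower with UO126, 1 up and 4 down of 6 (camera adjusted p = 0.038, and adjusted p = 0.32 with an estimated correlation). No other list passed against the empty vector with either drug, and these p-values were adjusted over the 48 list tests against it.

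The DMSO libraries enter both sides of this comparison, so chance alone opposes the fold changes. Across genes, which are not independent replicates, the fold changes of c-Fos correlated with those of afatinib at r = -0.357 and with those of UO126 at r = -0.372. Simulated groups with no effect gave -0.531 and -0.529, and simulations with the c-Fos effect and no inhibitor effect gave -0.176 for both. The covariances were -0.128 and -0.110, against -0.0216 and -0.0213 in the simulations, a difference of -0.106 and -0.0883. Independent lists of these sizes would share 596 genes for c-Fos up and afatinib down, 563 for the opposite pair, and 407 and 370 for UO126. Simulated unchanged groups shared at most 2 genes in any of these sets, but hardly any gene was called in them. Their counts therefore do not measure what shared controls add to real effects. The 2 DMSO libraries cannot be divided into parts of at least 2, so part of the excess over independent lists may come from the shared controls. With a different DMSO library in each comparison, tried after the results were seen, the correlations were -0.285 and -0.308 for afatinib and -0.284 and -0.301 for UO126.

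Both inhibitors changed many genes alike: 1397 were higher with both drugs and 1579 lower with both, against 378 and 407 for independent lists and at most 2 and 0 in simulated unchanged groups. Hardly any gene was called in those groups, so their counts do not show what shared libraries add when the drugs act. Without DMSO replicate 2, 1552 genes changed the same way with both. The fold changes correlated at r = 0.806 across genes (0.527 in the simulations), with a covariance of 0.181 against 0.0214, a difference of 0.160. With a different DMSO library for each drug the correlation was 0.671 or 0.664. Part of the excess over independent lists may come from the shared DMSO libraries. There were 45 genes with calls in opposite directions, 34 of them lower with afatinib and higher with UO126. No empty-vector group received an inhibitor, so an inhibitor effect that needs c-Fos was not separated from an effect that does not. Against the empty vector, 2792 genes were higher and 3017 lower with afatinib, and 2352 and 2502 with UO126. The lower counts with afatinib were 1953 and 1986 without empty vector replicate 1 or 2 and 1984 without afatinib replicate 2. Those with UO126 were 1476 and 1577 without empty vector replicate 1 or 2.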

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

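The use of the scaling without Rn45s, the limit of 0.1 under which a scaling or trend moves too little to test, the tests against the median of all genes and against genes near in GC content and length, and the reading of a bound against the spread of the members were chosen after the results were seen.

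Of 18 sterol synthesis genes, 8 were lower with afatinib and 12 higher with UO126, with 6 in both counts. Neither list call held with an estimated correlation (adjusted p = 0.18 and 0.075), while that of the difference between the inhibitors did (0.017). The list median of afatinib against UO126 was -0.60, and Mvd differed by -1.36 (afatinib -0.66 and UO126 0.71, each against DMSO). Lss differed by -1.04 (-0.30 and 0.74), Fdft1 by -0.91 (-0.42 and 0.50) and Cyp51 by -0.91 (-0.61 and 0.30). Outside that list, the same held for Cyp1b1 at -1.48 (-0.41 and 1.08), the keratin gene Krt6a at -0.73 (-0.45 and 0.29) and Hspa5, an endoplasmic reticulum chaperone gene, at -0.56 (-0.25 and 0.32). For each of these genes the edgeR test called both effects and, as opposite effects nearly ensure, their difference.

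For the sterol genes, the list median was -0.59 or lower under DESeq2 size factors and without Rn45s. These scalings moved the median of all genes by at most 0.0049, too little for a test by another scaling. After removal of the trend on GC content and length the list median was -0.58. The trend had an SD of 0.042 over all genes, also under the limit for a test by correction. It moved the list median by only 0.014, so the fitted trend itself does not account for a median of -0.60. A factor common to all genes of a library would leave the list at the median of all genes. The distance of the list from that median was -0.60 (SD of the members 0.32). That argues against such a factor for these genes. Camera had already called the list against the other genes on these values, so the distance restates that call and is no separate test. The median difference of 18 members from the 100 other genes nearest to each in GC content and length was -0.57 (SD 0.32). That argues against GC content and length as the whole cause. A biological candidate explanation is that cells held more sterol with afatinib than with UO126, in which case genes raised by oxysterols through LXR would be higher with afatinib. The 8 tested LXR targets other than Abca1 had a median of -0.029 with 0 higher and 2 lower, below the bound of 0 set in advance by less than their SD of 0.37, so this explanation stays open. The drugs also differ in target and dose, which this design cannot separate.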

How the results depend on the processing

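The omission of Rn45s was the only refit chosen after the results were seen. The correlations with a different DMSO library in each comparison, which were no refit, were also chosen then. Of 314 values of named genes 301 were called, and 276 of these kept their call and direction under every refit with another scaling, test, filter, set of libraries, replicate block or 1 library left out that tested them, with none reversed. The stricter low-count filter left 296 of the 314 to be tested. The other scalings moved the median log2 fold change of all genes by at most 0.014. Without a library, a group had 1 library, which was assumed to vary like the other groups. In simulated data 4-fold changes were recovered more often than 1.5-fold changes in each of the 4 comparisons, and depth was not varied. Replicate numbers are shared by the groups but mark nothing in the labels, and the correlations of deviations lay between -0.21 for afatinib and UO126 and 0.12 for the empty vector and DMSO. With the replicate block the counts higher and lower were 2554 and 2478 for c-Fos, 2527 and 2537 for afatinib, 1580 and 1652 for UO126 and 706 and 711 for afatinib against UO126. The list tests passed were 41 of 96 with the block against 42 without. The block ended the list calls of aryl hydrocarbon receptor targets with c-Fos (adjusted p = 0.051) and Wnt/beta-catenin targets with UO126 (0.052), and the gene calls of Map2k2 with c-Fos (0.056), Axin2 with UO126 (0.057), Pdgfra with afatinib (0.051) and UO126 (0.063) and Erbb2 between the inhibitors (0.058). It added the call of Mitf with UO126 (0.031) and that of cytokines between the inhibitors (0.047).

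The DESeq2 Wald test gave 559 genes lower with c-Fos and higher with UO126, against 850. Fitted to the compared libraries alone, afatinib against UO126 had 481 higher and 505 lower, against 919 and 920. With a 2-fold minimum the counts higher and lower were 494 and 512 for c-Fos, 346 and 279 for afatinib, 202 and 146 for UO126, and 26 and 50 between the inhibitors. At adjusted p under 0.01 they were 1001 and 1144 for UO126 and 378 and 408 between the inhibitors. List calls numbered 4 with an estimated correlation and 66 with fry, which asks another question. With no low-count filter the G1/S (adjusted p = 0.0082) and p53 (0.025) lists passed for c-Fos, and without robust estimation cytokines passed between the inhibitors (0.037). With 1 library left out, genes lower with c-Fos ranged from 1661 to 3085 and those lower with afatinib from 1692 to 3205. For UO126 the ranges were 913 to 2051 higher and 968 to 2063 lower, and between the inhibitors 391 to 1316 higher and 307 to 1102 lower. Against the empty vector, 1953 to 3232 genes were lower with afatinib and 1476 to 2452 with UO126. Genes higher with c-Fos and lower with an inhibitor ranged from 695 to 1703 for afatinib and 493 to 1136 for UO126. Those lower with c-Fos and higher with an inhibitor ranged from 652 to 1525 and 366 to 1020. Genes changed alike by both inhibitors ranged from 1552 to 3207. The lowest values came without DMSO replicate 2, empty vector replicate 1 or afatinib replicate 2, and the cause was not tested.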

Other observations

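The test with different DMSO libraries in the compared pairs, the limit of 0.1 under which a scaling moves too little to test, the tests against the median of all genes by SD and by standard errors, and the reading of a bound against the spread of the members were chosen after the results were seen, as were the genes named next.

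The edgeR test called 45 genes in opposite directions with the 2 inhibitors, each against the same DMSO libraries, which nearly ensures that their difference is called too. Besides sterol list members, those lower with afatinib and higher with UO126 included Fasn (difference -0.66) and Acly (-0.53) of fatty acid synthesis, the hyaluronan synthase gene Has2 (-1.24) and Wnt7a (-1.12). The stress genes Gadd45b (-0.92) and Gadd45g (-0.85) went the same way, while Gadd45a, as reported, was higher with afatinib. The 11 genes in the other direction included the metallothionein genes Mt1 (0.82) and Mt2 (0.84), which can share reads, the plasminogen activator gene Plat (0.84) and Arrdc4 (1.06).

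The ATF4 and unfolded protein response list held 12 ATF4 members and 8 members of the chaperone branches. With afatinib 10 of the ATF4 members were higher and 1 lower, with a median of 0.93, while 2 of the chaperone members were higher and 4 lower. With UO126 the ATF4 members had 9 higher and 0 lower, with a median of 0.63, and the chaperone members 5 higher and 0 lower, with a median of 0.32. Between the inhibitors, 8 ATF4 members were higher with afatinib and 1 lower (median 0.41). Of the chaperone members 0 were higher and 5 lower (median -0.49, camera adjusted p = 5.5e-07 over 16 tests, and adjusted p = 0.063 with an estimated correlation).

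The medians of the ATF4 members, 0.93 and 0.63, did not pass with an estimated correlation (adjusted p = 0.063 for each inhibitor in limma's camera). Their lowest value under the other scalings was 0.63, but these moved the median of all genes by at most 0.0058 and test nothing. A factor common to all genes would leave the members at that median. Their distance from it was at least 0.62 (SD 0.64 over members that differ from each other) and a median of at least 8.63 standard errors. Camera had already called their list against the other genes on these values. A distance from the median of all genes was thus nearly assured and is no separate test. A factor that moves all genes alike would still not set these members apart by that many standard errors, which argues against it for them. An unfolded protein response would raise the chaperone members too, whose median with afatinib was -0.091, under the bound of 0 set in advance but by less than their SD of 0.43, so this stays open. A wider ATF4 programme may be present, but 20 tRNA synthetase genes outside the list went both ways, 11 higher and 6 lower with afatinib (median 0.28) and 10 and 4 with UO126 (0.21). Limma's camera p of 0.027 and 0.023 met the bound set in advance, but the adjusted p was 0.062 and 0.061 over 16 tests and 0.68 for both with an estimated correlation, so this stays open.

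The genes raised by c-Fos that fell with the inhibitors are the last pattern weighed. Simulated libraries with the c-Fos effect alone gave at most 3 such genes for either drug. With no inhibitor effect simulated, hardly any gene could be called lower with an inhibitor, so this count was low by construction. It does not show what the shared libraries add when the inhibitors act. With different DMSO libraries in the 2 comparisons the correlation across genes was -0.28 at its weakest. That argues against chance values of single DMSO libraries as the whole cause. A deviation common to both DMSO libraries would remain in this split, so such a deviation was not tested. An inhibitor effect that does not need c-Fos may account for part of this pattern. Among genes not changed by c-Fos, 17.0% were lower with afatinib and 9.54% with UO126, against 47.8% and 37.9% of the c-Fos-raised genes. The c-Fos-raised genes were selected on high DMSO values, which by chance favours calls as lower. These shares therefore do not measure how much of the fall needs c-Fos. An inhibitor effect that does not need c-Fos cannot be told apart from an effect that does, because no empty-vector group received an inhibitor. Fos RNA itself was called lower with UO126, and whether this contributed to the falls with that drug was not tested.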
